A study of Rattus norvegicus with 4 samples.

How the data were processed

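Total RNA from rat liver was amplified, labelled with Cy5 and hybridised to single-colour arrays, per the labels' protocols. The deposited files held 1 array for each of 4 groups: transgenic, transgenic with luteolin, wild type and wild type with luteolin. Each array gave 20174 probes, 1 per Ensembl gene identifier, with a raw spot intensity, a background-subtracted intensity, a globally normalized intensity and a quality flag, per the file headers. Compared with the raw values, the authors' background-subtracted intensity was the raw intensity less 1 constant per array (37.5 to 39.8) and was blank where the raw value lay at or under about 1 unit above it. The authors' globally normalized intensity was that value times 1 factor per array, which put each array's median at 25. The series table held the same values rounded to whole numbers, since each lay within 0.500 of the sample files' value. Its scale is therefore linear and not centred. The scanner, its software and how the background constant was set are not given in the sources used here. Of the flags, 2 were other than OK, both on the transgenic luteolin array, and those spots were left out. The highest raw intensity was 60807, 43490, 44092 and 54437 on the transgenic, transgenic luteolin, wild-type and wild-type luteolin arrays.

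The raw intensities and the background constant were corrected with limma's normexp method with an offset of 50, taken to log2 and quantile normalized between the 4 arrays (R 4.3.3, limma 3.58.1). No blank or control spots were identified, so a probe counted as above background on an array where the authors gave a background-subtracted value, the last option of the rule fixed before the data were examined. Probes were named through the reference table of rat genes: 10681 by a curated transcript accession, 3106 by an Entrez identifier and 77 by another accession, 1503 and 209 by a file symbol that is a current symbol or a synonym, while 2519 kept the file's name, 1990 had none, and 89 with conflicting names were left unnamed. Where a gene had several probes (89 genes) the brightest was used, which left 20025 genes. Sequence positions are not given, since the files name no genome build.

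With 1 array per group, each comparison is a log2 ratio of 2 arrays, among genes above background on both, and counts of genes at 2-fold or more. Ratios carry no replicate check, and the number of arrays limits their precision. The median raw intensity was 54.4, 48.6, 48.0 and 51.5 on the transgenic, transgenic luteolin, wild-type and wild-type luteolin arrays, close to the background constant, so an offset of 50 shrinks ratios of dim genes. Over all arrays a limma model (lmFit and eBayes) with genotype and luteolin as additive terms was fitted to 14130 genes above background on all 4, with Benjamini-Hochberg adjustment, over all genes and over each list alone. It has 1 residual degree of freedom per gene, and its p-values rest on single samples, which may differ for technical reasons. With 35 lists and 2 effects, calls within lists were not corrected for the number of lists.

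Fixed gene lists covered 23 pathways and 12 cell types. For each list the median log2 ratio of members above background on all 4 arrays was set among 10000 random lists of the same size matched on mean intensity in 20 bins (2000 in alternatives), and a list outside the central 95% is described as above or below random lists. This describes these arrays and is no test between groups. Genes named by size come from the 10 largest ratios in each direction for luteolin in each genotype and for genotype without luteolin, 5 for genotype with luteolin, 5 per direction shared by both genotypes, and Gjb1. Up to 4 members of a list are given as examples in most cases, and further members called by the additive model. Genes with provisional names were not named. A gene is described as high or low on 1 array alone where it lay at least 0.7 (log2) from the median of the other 3 arrays and these lay within 0.4 of each other. Genes above background on 1 array of a luteolin comparison are given as bounds, with the lowest kept signal of the dim array as the floor.

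On simulated arrays, made from the real means with the real interaction residuals shuffled within bins and a luteolin effect given to 200 of 14130 genes, all drawn from those brighter than the median, the additive model called 27 of 100 genes planted at a log2 size of 1 and 74 of 100 planted at 2, with 0 unchanged genes called. With an intensity trend it called 100 of 100 at both sizes. The simulation added no noise to the luteolin coefficient, so unchanged genes had a coefficient of 0 and could not be called. These counts therefore say nothing about false calls, and power may be lower on real arrays. Dimmer genes were not planted, so power for them is unknown. For luteolin in transgenic rats, 7 of 200 unshifted lists of 20 genes lay outside the central 95%, and 188 of 200 shifted by 0.1. These lists held randomly drawn genes, so they do not show how often lists of genes that vary together lie outside. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest.

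Alternatives chosen before the data were examined were median centring or cyclic loess in place of quantile normalization, background subtraction with a floor, an offset of 16, no filter on dim probes, only the brighter genes, the authors' series values, the mean of a gene's probes, an intensity trend in the prior and no covariate. The authors' series values centred on the median difference, and leaving out 2 stretches of file rows that hold at least 4 genes low on 1 array alone, were added after seeing the data. Such low genes lay closer together in the file than random draws on the wild-type luteolin array, and this was not shown for low genes on the transgenic array. Genes high on 1 array alone were not used to set the stretches. File order stands in for position on the array, since the layout of spots is not given in the sources used here. The authors' scaling moved the median of all genes by -0.26 for luteolin in transgenic rats, 0.18 for luteolin in wild type and -0.42 for transgenic against wild type with luteolin, so directions of lists and named genes were checked relative to it, on the centred values.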

Results

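Liver RNA was profiled in rats with steatohepatitis brought on by diethylnitrosamine, a liver carcinogen given once rats were 10 weeks old, and a methionine-choline deficient diet fed for 12 weeks, which causes fat build-up, inflammation and scarring. Some rats received luteolin, a plant flavonoid, in that diet. Sprague-Dawley rats were either wild type or carried a transgene for a dominant negative form of connexin 32, the main gap junction protein of hepatocytes, encoded by Gjb1. There were 4 groups with 1 single-colour array each: transgenic, transgenic with luteolin, wild type, and wild type with luteolin. No group had a second array, so no ratio between arrays has a replicate check, and ratios below are described as higher or lower without a p-value. Sex, luteolin dose and whether an array held RNA of 1 rat or of several are not given in the sources used here. Each array had 20174 probes, of which 77.4% had a value above background on the transgenic array, 72.5% on the transgenic luteolin array, 76.0% on the wild-type array and 78.7% on the wild-type luteolin array. Between 55.4% and 59.4% of those probes lay under 50 intensity units above background, where the offset used here pulls ratios toward 0.

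Gjb1 itself had a log2 intensity of 10.07 on the transgenic array, 10.43 on the transgenic luteolin array, 10.40 on the wild-type array and 10.40 on the wild-type luteolin array. Its log2 ratio of transgenic against wild type was -0.34 without luteolin and 0.02 with it. Whether the probe reads the transgene as well as the endogenous gene is not given in the sources used here, so these values do not check the genotype labels. Gjb2, which encodes connexin 26, the partner of connexin 32 in hepatocyte gap junctions, was lower by a mean of 0.39 over both diets (log2 -0.39, SE 0.04). That difference passed limma's test on the additive model, with an adjusted p = 0.0237 when adjusted over the list alone (7 connexins) and 0.686 over all genes tested. None of the 7 measured connexins differed by 2-fold between any arrays compared, and the list's median lay within the central 95% of random lists in all 4 comparisons.

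The first question was how luteolin in the diet related to liver expression in transgenic rats. Genes of the phase II enzyme Gstp1, the placental glutathione S-transferase that marks preneoplastic foci in rat liver, and of the extracellular matrix were lower with luteolin. Gstp1 was 3.51-fold lower (log2 ratio -1.81), matrix Gla protein (Mgp) 2.82-fold lower (-1.49), and the fibrillar collagens Col3a1, Col1a2 and Col1a1 were lower by log2 ratios of -1.56, -1.39 and -1.33. Also lower were Ccn2 (connective tissue growth factor, -1.36), Loxl1 (a collagen cross-linking oxidase, -1.25), the aldo-keto reductase Akr1b8 (-1.27) and Bex1 (-1.25). The cytochrome P450 Cyp2c7 was 2.34-fold higher (1.23), as were the fasting hormone Fgf21 (1.19), the glycogen-targeting subunit Ppp1r3c (1.18), Gstp3 (1.03) and the beta-globin genes Hbb-b1, Hbb-bs and Hbb (1.10, 1.09 and 1.07), whose probes can share sequence. In all, 13 genes were 2-fold or more higher and 24 lower among 14333 compared. With each array centred on its median in place of quantile normalization, these counts were 8 and 43, and with the authors' values 159 and 1251. Of the genes above, Col3a1, Col1a2, Col1a1, Ccn2 and Loxl1 were high on the transgenic array without luteolin alone. Nup98 (1.55), Nr2f6 (1.40) and Galk1 (1.03) ranked among the genes higher with luteolin and Csnk2a2 (-1.60) among those lower, but each rested on a single array. Nup98, Nr2f6 and Galk1 were low on the transgenic array alone, and their probes lie between rows 2945 and 3259 of the deposited file. That stretch holds 4 of the 11 genes low on that array alone. Over the whole file, these 11 genes formed 1 pair within 50 rows (permutation p = 0.240). That count leaves out genes farther apart in the file, while deviations on this array correlated by 0.0547 at a distance of 105 rows and by -0.00822 at 50. Without the 2 stretches of the file that hold such genes, the count of higher genes in this comparison was 7.

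By gene group, 27 of the 28 measured fibrosis and matrix genes were lower with luteolin in transgenic rats, 7 of them by 2-fold or more, and the list's median log2 ratio was -0.62 (-0.59 to -1.18 over 9 alternatives). Basement membrane collagen Col4a1 (-0.98), Fbn1 (-1.20), Col6a1 (-1.11) and Timp1 (-0.87) were among these. Cell cycle genes were lower in 37 of 39 members, none by 2-fold (median -0.24, and -0.21 to -0.89 over 9 alternatives), with ratios of -0.88 for Cdca3, -0.71 for Kif20a, -0.66 for Rrm2 and -0.63 for Pcna. Cholangiocyte markers were lower in 11 of 12 members (median -0.21, and -0.19 to -0.84 over 9 alternatives), with Tspan8 at -0.86 and Epcam at -0.73. Stellate cell and myofibroblast markers were lower in 10 of 12 members (-0.18), endothelial markers in 7 of 10 (-0.11), neutrophil markers in 6 of 8 (-0.08) and T and NK cell markers in 13 of 17 (-0.04). The T and NK cell median turned to 0.08 under median centring, and these last 2 lists stood apart with the same sign in 6 of 9 alternatives each. The macrophage list had a median of -0.05, within the central 95% of random lists, although 3 of 17 members, Lyz2 (-1.22), Gpnmb (-1.17) and Lgals3 (-1.03), were lower by 2-fold or more. Col4a1, Fbn1, Col6a1, Cdca3, Tspan8, Gpnmb and Lgals3 were high on the transgenic array without luteolin alone. Antigen presentation genes (-0.15), liver tumour and progenitor genes (-0.11) and antioxidant genes of the Nrf2 list (-0.08) had medians below random lists.

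Metabolic lists went the other way. All 6 measured erythroid genes were higher with luteolin in transgenic rats (median 0.98), a list made up largely of globins that circulating red cells carry. Of 18 measured genes in the list of cytochrome P450 and related genes named for the receptors CAR and PXR, 16 were higher (0.27). Among them were Cyp3a23-3a1 at 0.98 and Cyp2a1 at 0.71. Whether each member is regulated by these receptors was not tested, so the list does not measure their activity. Lipogenic genes were higher in 15 of 17 members (0.22), including Thrsp (0.78) and the stearoyl-CoA desaturase Scd (0.60). Fatty acid oxidation genes were higher in 25 of 31 (0.20), including Cpt2 (0.65), the pyruvate dehydrogenase kinase Pdk4 (0.64) and Angptl4 (0.71). The lists of methionine, choline and one-carbon metabolism (0.18), hepatocyte function (0.14), bile acids (0.12) and the circadian clock (0.09) were also above random lists. Of the members named, Cyp3a23-3a1, Thrsp and Scd were low on the transgenic array alone and Angptl4 was high on the transgenic luteolin array alone. The hepatocyte list's median was -0.03 under median centring, and the circadian list stood apart in only 3 of 9 alternatives, with a lowest median of 0.01. In this comparison 18 of 35 lists lay outside the central 95% of 10000 random lists matched on expression, where 1.75 would lie outside at random. Random lists hold unrelated genes, while members of a real list can vary together. Real lists can therefore lie outside more often than that from differences between single samples, and lists also share members.

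**Figure D1:**
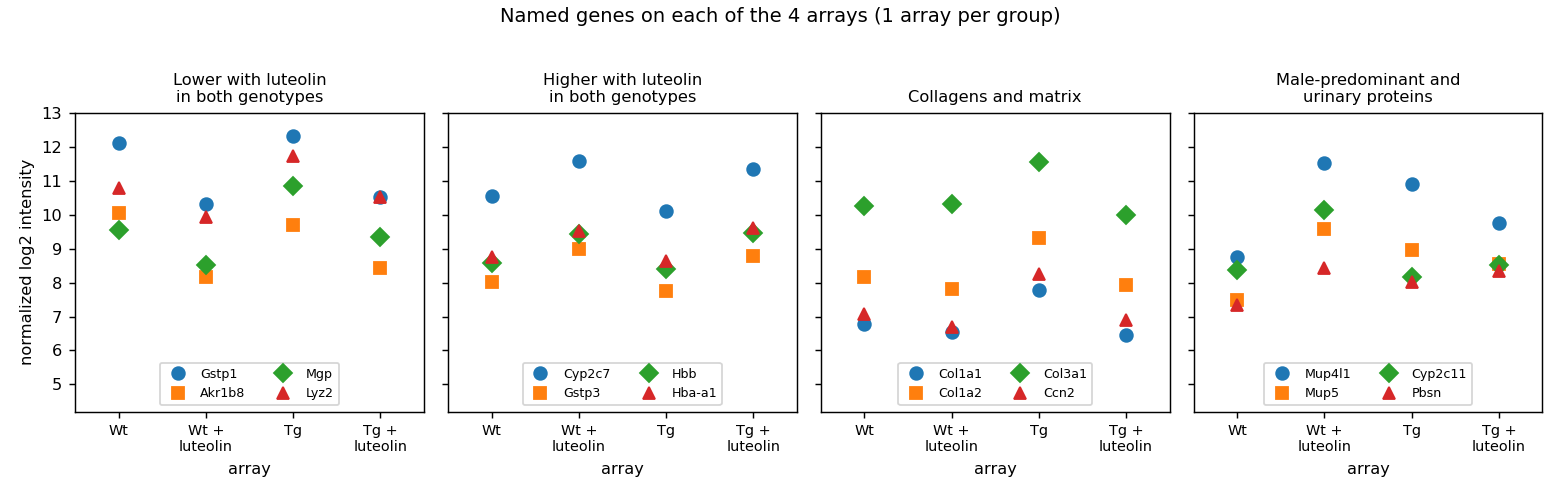
Normalized log2 intensity (vertical axis) of 16 genes on each of the 4 arrays (horizontal axis), 1 point per array, with no error bars because each group has 1 array. Gstp1 lies at 10.51 and 10.33 on the transgenic and wild-type luteolin arrays against 12.32 and 12.12 without luteolin, while the collagens are high on the transgenic array without luteolin alone.

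In wild-type rats the genes highest with luteolin were of another kind. Transcripts of the lipocalin family that binds pheromones and of male-predominant liver enzymes led: Mup4l1 was 6.75-fold higher (log2 ratio 2.75), Mup5 4.25-fold (2.09) and the male-specific cytochrome P450 Cyp2c11 3.42-fold (1.78), with probasin (Pbsn) at 1.10. Probes within the urinary protein family can share sequence. Cyp2c7 (1.03), carbonic anhydrase Car3 (1.00), glucose-6-phosphatase G6pc1 (0.97), Gstp3 (0.95), Rufy1 (1.30) and Sfxn2 (1.01) were higher as well. Rufy1, Sfxn2 and G6pc1 were low on the wild-type array without luteolin alone, and Cyp2c11 and Car3 were high on the wild-type luteolin array alone. Lower with luteolin were Akr1b8 (3.73-fold, -1.90), Gstp1 (3.46-fold, -1.79) and the glutathione transferase Gsta5 (-1.12).

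Counts in wild type were 10 genes 2-fold or more higher and 16 lower among 14801 compared. With median centring they were 18 and 12, and with the authors' values 642 and 265. Among the other lower genes, Arf3 (-1.55), Efna1 (-1.40), Ifi35 (-1.20), Fat1 (-1.19), Bcl10 (-1.18) and Rbm45 (-1.10) all have probes within 1 stretch of the deposited file, rows 11267 to 12523, where genes low on the wild-type luteolin array cluster. Car3, Fgf21 and Col1a1 also have probes in that stretch, and Mup4l1 has its probe at row 3089, within the stretch of genes low on the transgenic array. Without both stretches, 4 genes were 2-fold or more lower in place of 16.

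**Figure D2:**
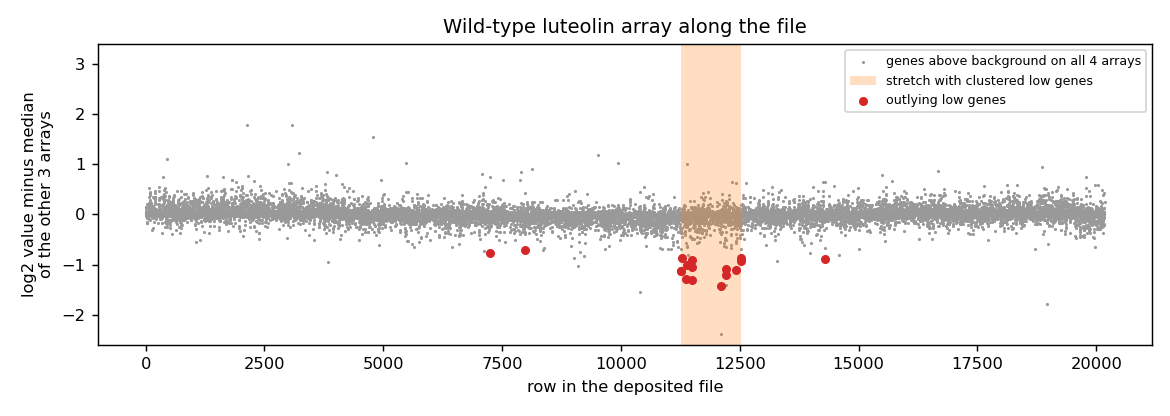
For each gene above background on all 4 arrays, log2 intensity on the wild-type luteolin array minus the median of the other 3 arrays (vertical axis) against its probe's row in the deposited file (horizontal axis). Red points are the 17 genes that were low on this array and alike on the others, and the shaded band is the stretch of 1257 rows that holds 14 of them.

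Among the lists in wild type, all 7 male-predominant genes were higher with luteolin (median 0.44), with Cyp2c11 and Mup5 past 2-fold and with Igf1 at 0.56, Cyp2a2 at 0.44 and Hsd3b5 at 0.39. All 6 erythroid genes were higher too (0.34). Medians of the CAR and PXR list (0.16), fatty acid oxidation (0.14), lipogenesis (0.12), hepatocyte function (0.12) and bile acids (0.09) were above random lists, bile acids in only 4 of 9 alternatives. Cell cycle genes were lower in 35 of 39 members (-0.12), cholangiocyte markers in 10 of 12 (-0.11), antigen presentation genes in 10 of 14 (-0.20), and liver tumour and progenitor genes in 14 of 19 (-0.10). RT1-A2 (-0.87), an antigen presentation gene, has its probe in the stretch of clustered low genes. The fibrosis list had a median of -0.06, with 20 of 28 members lower and none by 2-fold. Stellate markers (-0.10), acute phase genes (-0.11) and 3 skeletal muscle markers (-0.07, in 5 of 8 alternatives) were also below random lists. This made 15 of 35 lists outside the central 95%.

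Luteolin's ratios in the 2 genotypes share no array and can be compared, as can the genotype ratios of the 2 diets. Cyp2c7 was higher by 2-fold or more in both genotypes, and Gstp1, Akr1b8 and Mgp were lower. That is 1 gene higher and 3 lower, against 0.00920 and 0.0272 for independent lists of these sizes among 14130 genes, while 1 gene went opposite ways by 2-fold or more against 0.0317. At 1.5-fold, 10 genes were higher and 14 lower in both, against 0.218 and 0.583, while 7 went opposite ways against 0.735. These expectations take every gene as equally able to reach the cut, although all genes at 2-fold with luteolin lay at or above the median brightness. Opposite overlaps exceeded them too, so an overlap above them does not by itself show a shared response. Gstp3 (1.03 and 0.95 in transgenic and wild type), Hbb (1.07 and 0.85), Hba-a1 (0.99 and 0.77) and the acyl-CoA synthetase Acsm5 (0.97 and 0.65) followed Cyp2c7. Lysozyme Lyz2 (-1.22 and -0.87) and the metalloproteinase Mmp27 (-0.80 and -0.94) followed the 3 lower genes. Across genes, which are not independent replicates, the ratios correlated with r = 0.22, and with r = -0.14 under median centring.

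**Figure D3:**
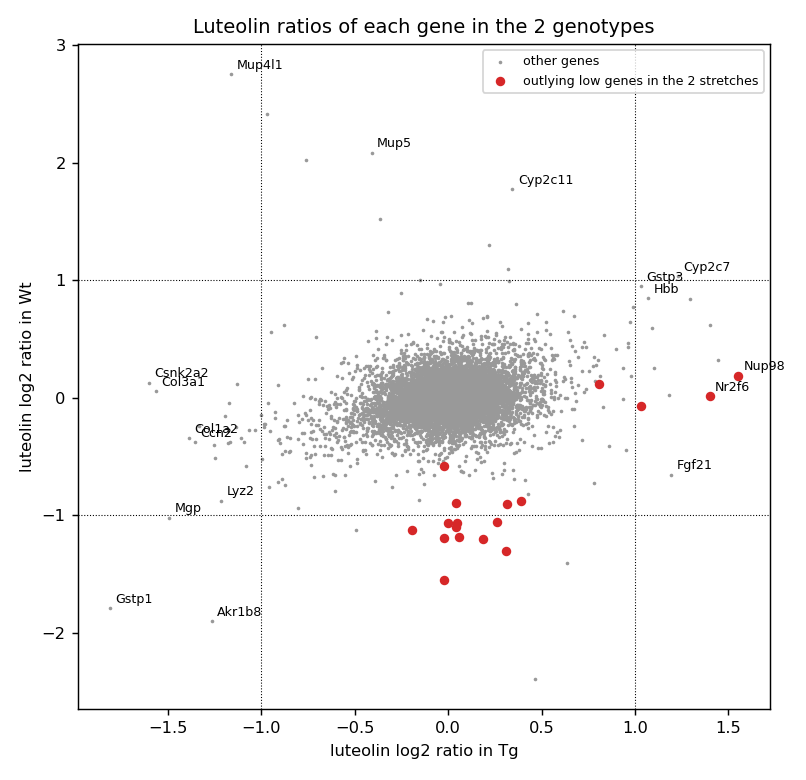
Luteolin log2 ratio in transgenic rats (horizontal axis) against that in wild-type rats (vertical axis), 1 point per gene above background on all 4 arrays, with dotted lines at 2-fold. Gstp1, Akr1b8 and Mgp lie low on both axes, Cyp2c7 high on both, and red points mark genes of the 2 stretches low on a single array.

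The additive model asked whether the mean luteolin difference over both genotypes exceeded the residual, which holds the genotype-by-luteolin interaction and the spread between samples with 1 degree of freedom per gene. No gene passed an adjusted p of 0.05 in limma's test over all 14130 genes, while 1215 had an unadjusted p under 0.05 and the smallest adjusted p was 0.560. When adjusted over the list alone, 26 genes in 12 of the 35 lists passed, 8 higher and 18 lower with luteolin, and every value below is so adjusted. Gstp1 fell by 1.80 (SE 0.04, adjusted p = 0.000944 among tumour and progenitor genes and 0.00159 in the Nrf2 list). In the Nrf2 list Akr1b8 fell by 1.58, Akr7a3 by 0.40 and Nqo1 by 0.38 (adjusted p = 0.0420 each). Among fibrosis and matrix genes, Timp1 fell by 0.81, Timp2 by 0.67, the macrophage elastase Mmp12 by 0.86 and vimentin (Vim) by 0.81 (SE 0.04 to 0.07, adjusted p = 0.0149 each), and the collagens did not pass. The macrophage genes Lyz2 (-1.04), Trem2 (-0.63), Tyrobp (-0.55) and Cd9 (-0.39) fell, as did the progenitor or biliary genes Krt19 (-0.60), Epcam (-0.61) and Prom1 (-0.57), RT1-Da (-0.50), Fcgr2b (-0.44) and the fatty acid carrier Fabp4 (-0.59). Cyp2c7 rose by 1.13 (SE 0.07, adjusted p = 0.0151), and Cyp2a1 (0.57), Cyp3a9 (0.36), Cyp2e1 (0.35), Cyp2c23 (0.30), Pdk4 (0.60), Hbb (0.96) and Hba-a1 (0.88) rose too. With an intensity trend in limma's prior, 328 genes passed over all genes tested, 78 higher and 250 lower. Under that prior 13 of 28 fibrosis genes, 18 of 39 cell cycle genes and 5 of 12 cholangiocyte markers passed over all genes, but so did Nup98 (adjusted p = 0.00500), whose ratio came from 1 array.

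The second question was how the transgenic liver differed from wild type on the same diet. Without luteolin, matrix genes were higher in the transgenic rat: Mgp 2.46-fold (1.30), Col3a1 2.45-fold (1.29), Ccn2 (1.18), Col1a2 (1.14) and the protease inhibitor Serpine2 (1.12). Lpin1, a phosphatidate phosphatase of triglyceride synthesis, was 2.95-fold higher (1.56), and Pck1, a key enzyme of gluconeogenesis, 2.38-fold (1.25). Mup4l1 (2.14), Mup5 (1.48) and Sfxn2 (1.38) were higher as well. The glycogen-targeting subunit Ppp1r3c was 3.30-fold lower (-1.72), and genes of lipid handling were lower: the carnitine acyltransferases Crat (-0.88) and Cpt1a (-0.86), Scd (-0.87), the lipid droplet coat protein Plin2 (-0.86) and the bile acid hydroxylase Cyp8b1 (-0.87). Aspg was at -1.08. Nup98 (-1.55), Nr2f6 (-1.51) and Galk1 (-1.11) were lower too, and these 3 genes, Aspg, Scd and Cyp8b1 were low on the transgenic array alone. Col3a1, Ccn2, Col1a2 and Serpine2 were high on that array alone, and Sfxn2 was low on the wild-type array alone. In total 19 genes were 2-fold or more higher and 7 lower among 14728, and the lower count was 2 without the 2 stretches. The authors' values gave 713 higher and 328 lower, and 301 and 328 when centred on the median difference. Their median ratio was already 0 here before centring. These values are rounded to whole numbers and ratios of exactly 2-fold were counted, so a small shift can move the count. The fall to 301 therefore does not show that the excess of higher genes was lost. This comparison and that of luteolin in transgenic rats use the same transgenic array, so a gene high on that array by chance is high here and low there.

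All 28 fibrosis genes were higher in transgenic rats without luteolin, 3 by 2-fold or more (median 0.55), and all 12 cholangiocyte markers (0.28), with Tspan8 at 0.78. Macrophage markers were higher in 14 of 17 (0.23), including Lgals3 (1.03), Gpnmb (0.98) and Lyz2 (0.94). Cell cycle genes were higher in 37 of 39 (0.15), and medians of the tumour and progenitor (0.11), immediate early (0.11), antigen presentation (0.10), stellate (0.10), T and NK cell (0.04), neutrophil (0.05) and NF-kB inflammation (0.04) lists and of 3 adipose markers (0.35) were above random lists. Lower were lipogenesis (15 of 17 members, median -0.26), cholesterol synthesis (16 of 18, -0.24), lipid droplet and transport genes (-0.16), fatty acid oxidation (25 of 31, -0.14), one-carbon metabolism (-0.11), hepatocyte function (-0.10), bile acids (-0.10) and erythroid genes (-0.17). That is 20 of 35 lists. The medians of the T and NK cell, neutrophil and NF-kB lists turned below 0 under median centring, and that of bile acids turned to 0.03 without the 2 stretches. The bile acid list stood apart with the same sign in 4 of 9 alternatives, the neutrophil list in 2 of 9 and the antigen presentation list in 5 of 9.

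**Figure D4:**
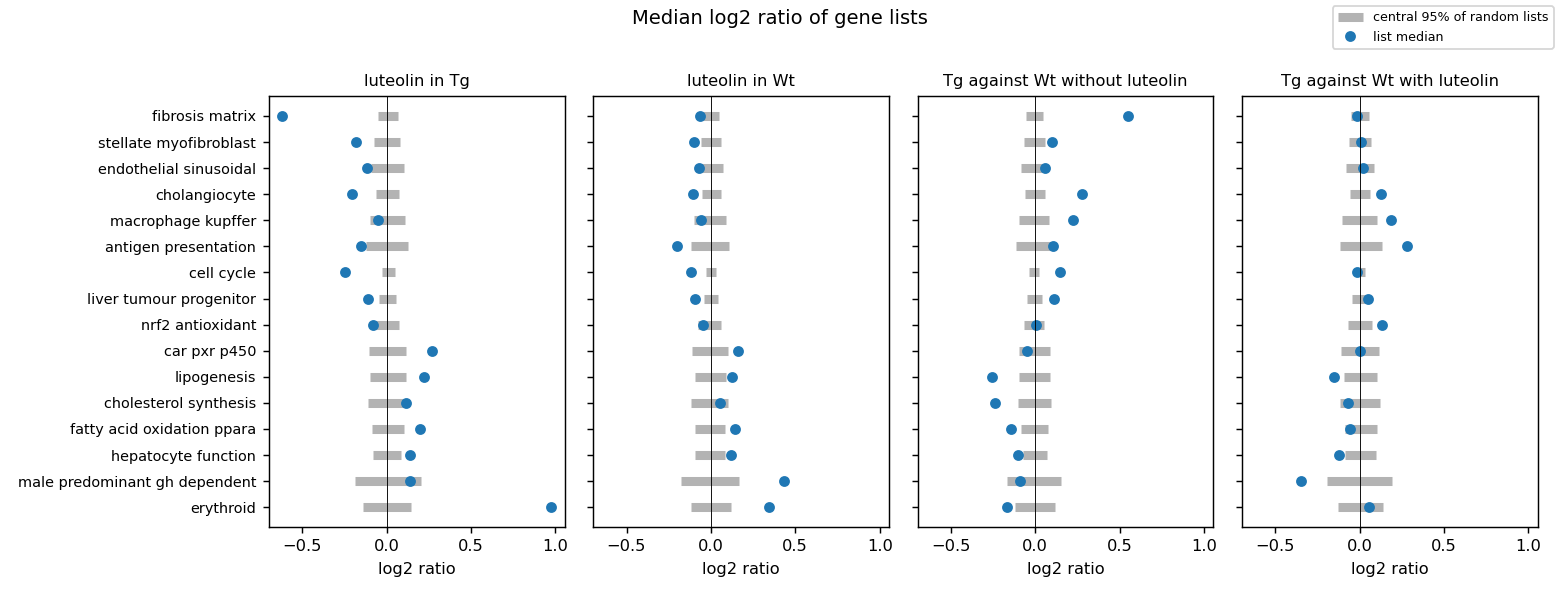
Median log2 ratio of 16 gene lists (blue points, horizontal axis) in the 4 comparisons, with grey bars for the central 95% of 10000 random lists of the same size matched on expression. The fibrosis list lies at -0.62 with luteolin in transgenic rats and 0.55 in transgenic against wild type without luteolin, and near 0 in the others.

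With luteolin in both groups, fewer lists stood apart between genotypes. Cyp2c11 was 3.06-fold lower in transgenic than wild-type rats (-1.61), as were Mup4l1 (-1.77), the transcriptional repressor Bcl6 (-1.51) and the acyl-CoA thioesterase Acot1 (-1.10). Csnk2a2 (-1.76) was low on the transgenic luteolin array alone. Among genes higher in transgenic rats, Efna1 (1.57), Arf3 (1.40), Ifi35 (1.36) and Fat1 (1.29) have probes in the stretch where genes were low on the wild-type luteolin array. Counts were 15 higher and 9 lower among 14387. Under median centring they were 9 and 23, with the authors' values 110 and 1271 and with those centred 242 and 233, and without the 2 stretches 0 genes were higher by 2-fold.

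Antigen presentation genes were higher in transgenic rats with luteolin in 11 of 14 members (median 0.28), macrophage markers in 14 of 17 (0.18), and the Nrf2 list (0.13), cholangiocyte markers (0.13) and tumour and progenitor genes (0.05) were above random lists. Male-predominant genes (-0.35), lipogenesis (-0.15) and hepatocyte function (-0.12) were below them. The fibrosis list had a median of -0.02, with 13 of 28 members higher. Medians of the Nrf2 and macrophage lists turned to -0.09 and -0.02 under median centring.

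In the additive model, no gene passed for genotype over all 14130 genes in limma's test (1018 with an unadjusted p under 0.05), and 151 passed with an intensity trend, 101 higher and 50 lower. When adjusted over the list alone, 19 genes passed, 14 higher and 5 lower in transgenic rats. Cpt1a fell by 0.83 and Crat by 0.82 (SE 0.04 and 0.05, adjusted p = 0.0150 each), Hmgcs1, the entry enzyme of the mevalonate pathway, by 0.54 (adjusted p = 0.0278), and the glutathione-degrading enzyme Chac1 by 0.71 (adjusted p = 0.0499). Timp2 rose by 0.54 (adjusted p = 0.0370), Lyz2 by 0.77, Cd9 by 0.55, Tyrobp by 0.39, Cd74 by 0.58, RT1-DMa by 0.52, Anxa2 by 0.64, Prom1 by 0.54, Krt19 by 0.37, Anxa4 by 0.40, Cd24 by 0.38, Gadd45g by 0.73, Dusp1 by 0.74 and Ier3 by 0.37, each with an adjusted p under 0.05. Over all genes the adjusted p of these was 0.686. Under the alternatives none of these genotype coefficients changed sign, but some moved toward 0 and some away. The lowest values were 0.17 for Ier3, 0.18 for Anxa4, 0.17 for Tyrobp and 0.31 for Cd74, while Chac1 reached -1.55. The genotype ratios without and with luteolin correlated across genes with r = 0.12, and with r = -0.21 under median centring.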

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

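The results here are genes whose ratio was 2-fold or more in opposite directions in the 2 genotypes or the 2 diets. The check of Y-linked genes became a count after none was found on the array, and the other test below was chosen before its result was seen, although the ratio of Cyp2c11, 1 of its genes, was known. None of the differences was tested, since each ratio rests on 2 arrays. Mup4l1 had a luteolin log2 ratio of -1.16 in transgenic and 2.75 in wild-type rats, a difference of -3.92. Its probe lies at file row 3089, within the stretch of rows 2945 to 3259 that holds genes low on the transgenic array alone, and it has no value in the alternative without the stretches. Its ratio of transgenic against wild type was -1.77 with luteolin and 2.14 without, which is the same difference of -3.92 seen from the other side. Mup5 had ratios of transgenic against wild type of -1.02 with luteolin and 1.48 without, a difference of -2.50.

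Mup4l1 and Mup5 belong with a wider pattern, the male-predominant genes that were higher with luteolin in wild type. Probes sharing sequence within the urinary protein family might carry such a pattern. The 6 list members outside that family had a median ratio of 0.41, at percentile 100 of random lists, whose upper bound was 0.17. They made up most of the list, whose median with Mup5 was 0.44, so this outcome was largely set beforehand. It shows that the list's median did not rest on Mup5. For Mup4l1 and Mup5 themselves, shared sequence stays open. A liver of the other sex or a mixed sample among the wild-type arrays stays open and cannot be told apart from luteolin, because 0 Y-linked genes were among the named genes of the array. Cyp2c11 was higher by 1.78 and Cyp2a2, Slco1a1 and Hsd3b5 by 0.44, 0.11 and 0.39, but how far their levels differ between sexes was not measured here. A luteolin effect and differences between single samples in growth hormone state are also untested.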

How the results depend on the processing

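No paired analysis was possible because each group has 1 array and the labels give no replicate numbers. No array could be left out, since 3 arrays leave the additive model no residual. The authors' values centred on the median difference and the results without the 2 stretches of file rows with genes low on 1 array were chosen after the data were seen. Of 546 list medians under the alternatives, 483 were the same by side and by standing apart, 54 were weaker and 9 reversed. Lists that stood apart with the same sign in fewer than 6 alternatives were, for luteolin in transgenic rats, the circadian clock (3 of 9), for luteolin in wild type, bile acids (4 of 9) and skeletal muscle (5 of 8), and between genotypes without luteolin, neutrophils (2 of 9), bile acids (4 of 9), adipose (4 of 7) and antigen presentation (5 of 9). Of 606 ratios of named genes, 574 were the same and 32 moved by over 1.5 times, all away from 0 and under alternatives with a smaller or no offset. The farthest values for luteolin in transgenic rats were -3.40 for Csnk2a2 (-1.60 with offset 50), 2.70 for Nup98 (1.55), 2.43 for Nr2f6 (1.40), -2.26 for Col1a1 (-1.33), -2.01 for Loxl1 (-1.25) and -1.98 for Bex1 (-1.25). In wild type they were -2.68 for Rbm45 (-1.10), 2.48 for Rufy1 (1.30) and -1.81 for Ifi35 (-1.20). Between genotypes without luteolin they were -2.70 for Nup98 (-1.55), -2.57 for Nr2f6 (-1.51) and -1.91 for Aspg (-1.08), and with luteolin -3.61 for Csnk2a2 (-1.76), -2.28 for Bcl6 (-1.51) and 1.97 for Ifi35 (1.36). Additive coefficients of genes passing over a list alone kept their sign but also moved, some toward 0 for genotype. For luteolin, Cyp3a9 (0.36) reached 1.41.

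Counts of genes 2-fold or more higher and lower follow for luteolin in transgenic rats (13 and 24 under quantile normalization with offset 50), luteolin in wild type (10 and 16), transgenic against wild type without luteolin (19 and 7), the same with luteolin (15 and 9), and both luteolin comparisons together (1 and 3). With the background subtracted to a floor and no offset they were 182 and 360, 114 and 189, 263 and 148, 171 and 91, and 8 and 47. That alternative changed the background method and dropped the offset at once, and which of these moved the counts was not tested. With offset 16 alone changed they were 25 and 72 for luteolin in transgenic rats, 37 higher between genotypes without luteolin and 2 higher in both luteolin comparisons. The authors' values, which carry no offset and shift the median, gave 159 and 1251, 642 and 265, 713 and 328, 110 and 1271, and 31 and 85. Centred on the median difference they gave 189 and 521, 177 and 293, 301 and 328, 242 and 233, and 10 and 61. Each array was centred against the mean of all arrays. Between genotypes without luteolin the median ratio was already 0 before that. The fall there from 713 to 301 higher may hinge on ratios of whole numbers at exactly 2-fold, which was not tested.

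Under median centring the counts were 8 and 43 for luteolin in transgenic rats, 18 higher in wild type, 9 and 23 between genotypes with luteolin, and 2 higher in both luteolin comparisons. The correlations across genes were -0.138 for luteolin and -0.208 for genotype, and the additive model called 108 genes for luteolin and 54 for genotype. List medians that changed side there were NF-kB inflammation (-0.00389), T and NK cells (-0.0644) and neutrophils (-0.0320) between genotypes without luteolin, Nrf2 (-0.0857) and macrophages (-0.0223) between genotypes with luteolin, and hepatocyte function (-0.0323) and T and NK cells (0.0814) for luteolin in transgenic rats. The cause was not tested.

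Without the 2 stretches, 7 genes were higher with luteolin in transgenic rats, 4 lower with luteolin in wild type, 2 lower between genotypes without luteolin and 0 higher with it, because the genes left out had been counted. The bile acid list's median between genotypes without luteolin was then 0.0258. Additive calls, 0 for both effects, were 131 for luteolin and 24 for genotype with the subtracted floor, 1 for luteolin with offset 16, 1 for luteolin among the brighter genes, and 328 and 151 with an intensity trend in the prior. Among the brighter genes the neutrophil median between genotypes without luteolin was -0.00199. The cause of these was not tested. Between 55.4% and 59.4% of probes above background lay under 50 units over it, which limits the ratios of dim genes.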

Other observations

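The test of close pairs in the file was chosen after the result was seen, as were the choice of the stretches and the distances searched for correlation along the file, and the other 3 tests before.

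Among genes above background on only 1 array of a luteolin comparison, bounds were small. In transgenic rats, 131 genes were above background only on the luteolin array and 885 only on the array without luteolin. Nat8l, Slc9a8 and Spem2 were at least 1.20-fold, 1.16-fold and 1.08-fold higher, and Crygn, Ncam1 and Lypd1 at least 1.22-fold, 1.19-fold and 1.12-fold lower. In wild type, 723 genes were above background only on the luteolin array and 296 only on the array without luteolin. In both genotypes the larger count lay on the array with more probes above background. These shares were 72.5% with and 77.4% without luteolin in transgenic rats, and 78.7% and 76.0% in wild type. The counts therefore do not show genes turned on or off by luteolin. There Barhl2, Kalrn and Ucp3 were at least 1.69-fold, 1.10-fold and 1.08-fold higher, and Tsbp1, Txndc2 and Zg16 at least 1.20-fold, 1.15-fold and 1.14-fold lower.

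Methionine and choline genes, whose substrates the diet lacks, were not all alike. In transgenic rats Cth (0.66), Gnmt (0.56), Bhmt (0.51) and Chdh (0.43) were higher with luteolin, while in wild type Cth was at 0.44, Bhmt at 0.06, Gnmt at -0.38 and Chdh at -0.25. Lists of random size-matched genes enclosed the wild-type median of -0.05. The transgenic array without luteolin carried much of the list structure: 21 of 35 lists stood apart on it when set against the mean of the other 3 arrays, against 18 on the wild-type luteolin array, 12 on the wild-type array and 7 on the transgenic luteolin array.

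A set of 17 genes was low on the wild-type luteolin array and alike on the other 3. They formed 9 pairs within 50 file rows, against a median of 1 and a maximum of 5 in 10000 random draws. The permutation p was 0.0001, the smallest these draws can give. A defect at spots that lie close together would give this if the file's order follows the array. The layout of spots is not given in the sources used here, so closeness on the array was not measured. The other 875 genes of the stretch had a median deviation of -0.0273 there, within the central 95% of windows of that length (-0.04 to 0.05). That argues against a defect over the whole stretch of file rows. On the transgenic array, 11 genes low there alone formed 1 close pair (permutation p = 0.240) and 45 high there alone formed 10 (permutation p = 0.0284). Pairs were counted within 50 rows only, while deviations along the file correlated again at greater distances, with peaks of 0.0547 at 105 rows on the transgenic, 0.0738 at 106 on the transgenic luteolin, 0.0771 at 98 on the wild-type and 0.126 at 102 on the wild-type luteolin array. Genes about that far apart, such as those low on the transgenic array between rows 2945 and 3259, are not counted as neighbours, so that count leaves a defect there open. Spot-level damage may therefore explain low values of Arf3, Ifi35, Fat1, Bcl10 and Rbm45 as a hypothesis, and a luteolin effect on these genes was not tested apart from it.

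Matrix genes were high on the transgenic array without luteolin. The 45 genes high there alone include Col1a1, Col1a2, Col3a1, Ccn2 and Loxl1. They formed 10 close pairs in the file, against a median of 5 in random draws (permutation p = 0.0284). The stretches left out were set by low genes only, so a defect at close spots was not tested for these high genes. A smaller share of hepatocytes in the sampled piece was predicted to raise markers of other cell types alike. The fibrosis list lay 0.49 above the endothelial list on that array (medians 0.59 and 0.10, bootstrap SE 0.15, 28 and 10 genes). Medians without the offset were 1.14 and 0.28. The bootstrap resampled genes of 1 array, so its SE is no spread between samples. Against wild type without luteolin, cholangiocyte (0.28) and macrophage markers (0.23) were higher and hepatocyte function (-0.10) was lower. Cell types need not rise equally, so the endothelial list alone cannot set a difference in cell shares aside. For the normalization between arrays as the cause, the fibrosis list's median on the transgenic array was taken under 5 alternatives. It stayed between 0.62 and 1.17, at percentile 100 of random lists in each. Those lists were matched on intensity, and the alternatives act largely alike on genes of like intensity, so the percentile could hardly change. The list thus lay above genes of like intensity under each, but the percentile cannot by itself set normalization aside. Matrix production by stellate cells in that sample, with genotype or as a difference between single samples, may be one hypothesis, and luteolin, genotype and the single sample cannot be separated with 1 array per group. Other markers on this array went the same way to a lesser degree, so part of the pattern in those lists stays open.

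The 4 arrays can be split 2 against 2 in 3 ways, too few for any share under 0.05. With the intensity trend, the luteolin split called 328 genes, the genotype split 151 and the remaining split, which is the interaction, 0. The interaction split had genotype as its covariate, so its residual was the luteolin difference, while the interaction was the residual of the others. A gene whose luteolin difference well exceeds its interaction cannot be called there. Its 0 is therefore no control for the other counts. Without the trend all 3 splits called 0 genes.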
